A study of Mus musculus with 2 samples.

How the data were processed

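H3K9ac ChIP-seq was done on limb tissue of mouse embryos at embryonic day 12.5, in 2 biological replicates, per the labels; the labels name matching control experiments, which were not used here. The deposited files are 4 peak lists in narrowPeak form on mm10: 1 per replicate, 1 called on both replicates pooled, and 1 of replicated peaks. Every one of the 33225 lines of the replicated list is also a line of the pooled list, so its values come from the pooled call. The aligner, the peak caller, their settings and the read totals are not given in the sources used here. The peak values were left as deposited and were used to describe, rank and filter peaks, with the limit that a value from one list is on that list's own scale.

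The unit of each column was settled from the values. The deposited fold enrichment is the ratio of the fragment pileup at the summit to the local background, each plus 1 pseudocount, and the next column holds the authors' −log10 p of a Poisson upper tail. With this reading, both columns together gave back a whole-number pileup for 100% of the peaks in each of the 4 lists, within 0.001 in −log10 p. The authors' −log10 q column was used only for a stricter threshold of at least 2, and the summit offset column was not used. The lists start at a −log10 p of about 2, a loose threshold: 63.6% of the peaks of replicate 1, 65.1% of replicate 2, 74.7% of the pooled list and 98.4% of the replicated list had a −log10 q of at least 2. The most frequent background, in fragments per position, was taken as a measure of relative depth: 2.77 in replicate 1, 2.02 in replicate 2 and 4.79 in the pooled list. Median summit pileups were 12, 10, 17 and 29 fragments in the lists of replicate 1, replicate 2, the pooled reads and the replicated peaks, so that a typical weak peak rests on few fragments. The deeper replicate also reaches lower folds at the same p, which affects counts of peaks taken from each list alone.

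Genes came from the GENCODE M21 basic annotation of the same build, with 41408 distinct start sites of coding transcripts of 21851 coding genes. A promoter peak is one with an edge or its body within 1 kb of such a start site, and the highest fold was kept where a gene had several. A distal peak lies over 5 kb from any coding start site and was assigned to the nearest one within 100 kb. Domains are replicated peaks merged when at most 1 kb apart. CpG observed/expected and GC content were taken from the reference sequence in 1 kb around the 5'-most start site of each gene. Peaks outside assembled chromosomes were left out of region and gene counts.

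Overlaps between lists needed at least 1 bp (bedtools 2.31.1). The share of peaks at promoters was set against 1000 random placements within the same chromosome. Gene lists were compared with all other coding genes by Fisher's exact test, two-sided, and medians or means by two-sided permutation tests with 100000 resamples, with Benjamini-Hochberg adjustment over the 20 lists or over those with at least 5 marked members. Intervals of shares are exact binomial and those of pileups exact Poisson, both at 95%. Tests across genes or peaks describe this tissue: genes and peaks are not replicates, and with 1 group of 2 samples no test between conditions was possible. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. In tests on simulated data, whole-number pileups were recovered for 100% of 2762 simulated peaks, and all of 200 genes given a peak at a start site were found. The simulated peaks all had a lower −log10 p than the 20 strongest promoter peaks. Recovery at peaks as strong as those was not simulated. The list permutation test, run on 13000 simulated genes, called 3% of 100 unchanged lists of 20 genes and 98% of 100 lists raised by a factor of 2. The simulated genes had independent values, and calls used the unadjusted p. These shares therefore do not carry over to adjusted calls, to shorter lists or to lists whose genes share peaks.

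The 20 gene lists, the tests and the alternatives were fixed before the data were examined. They hold Hox genes, limb transcription factors, limb signalling, ectoderm, chondrogenic, late osteoblast and hypertrophic, myogenic, tendon, endothelial, erythroid, macrophage, Schwann cell and melanocyte, neuron, liver, cardiac, foregut with pancreas and gut, pluripotency and germ cell, housekeeping, cell cycle, and olfactory with vomeronasal receptor genes. The erythroid list was used with 15 members because Ahsp was not found in the annotation. By the rule for named genes, the text names list members with and without a peak, the genes at the 20 strongest promoter peaks, the nearest genes of the 10 strongest distal peaks, the genes in the 10 widest domains, and the 5 genes with the largest replicate ratio in each direction among those with a mean fold of at least 4. The alternatives were other peak lists (pooled, or each replicate's own, which leaves out the other replicate), the stricter −log10 q, windows of 500 bp and 2.5 kb, start sites of all annotated genes, other overlap rules, and other distances for distal peaks (2.5 kb), assignment (50 kb) and merging (none, or 3 kb).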

Results

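Acetylation of lysine 9 of histone H3 (H3K9ac), a chromatin mark found mainly at active promoters and enhancers, was mapped by chromatin immunoprecipitation and sequencing in limb tissue of mouse embryos of the B6NCrl strain at embryonic day 12.5. At this stage the limb bud holds proliferating mesenchyme, forming cartilage, developing muscle and a covering ectoderm. The samples form 1 group of 2 biological replicates, pools of male and female tissue from 88 embryos (replicate 1) and 68 embryos (replicate 2). There was no second condition, so the comparisons are between the replicates and between genes and regions within the tissue. The lists held 91937 peaks for replicate 1, 74158 for replicate 2, 89695 for both pooled, and 33225 peaks that the authors kept as replicated. Genome-wide background was 2.77 fragments per position in replicate 1 and 2.02 in replicate 2, a ratio of 1.37, and the pooled list had 4.79. Positions are on mm10. Unless another list is named, a fold is the authors' own value for the strongest replicated peak within 1 kb of a start site of the gene, taken from the pooled reads, and a mean ± SD is over the values in both replicates' own lists (n = 2).

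The replicates were compared first, for whether they marked the same regions and promoters. Several limb promoters had a high fold in both: the peak over Hoxa10 and Hoxa11 had a fold of 46.3 ± 2.79 (SD, n = 2), that of the mesenchymal homeobox gene Prrx1 38.6 ± 3.06 (SD, n = 2) and that of the cartilage regulator Sox9 25.5 ± 2.90 (SD, n = 2). Across the 13889 coding genes with a promoter peak in both lists, fold values had a Spearman correlation of 0.905 (95% bootstrap interval 0.902 to 0.908) and a Pearson correlation of 0.906 on the log2 scale. These are across genes, which are not independent replicates. Fold was higher in replicate 1, with a median log2 ratio of 0.27 and an SD of the log2 ratio of 0.35, and 81.6% of the genes lay within 1.5-fold. At equal enrichment over background, the added pseudocount makes the fold higher in the list with the higher background (2.77 against 2.02). The higher fold is therefore not by itself a measure of stronger signal, and the difference enters each mean ± SD. A further 925 genes had a promoter peak in the list of replicate 1 alone and 365 in that of replicate 2 alone. The widest gaps were at C2cd4d (15.1 in replicate 1 and 2.98 in replicate 2), Gm49027 (13.8 and 3.52), Armc9 (13.5 and 3.74), Map3k6 (12.5 and 3.49) and Kbtbd11 (8.23 and 2.56) in one direction. In the other direction they were at Armcx3 (3.52 and 11.2), Pinlyp (3.68 and 11.2), Jrkl (2.75 and 6.95), Mfsd4b2 (3.73 and 9.39) and Hgf (2.58 and 6.29). The strongest peak near the start site was taken separately in each list, and at C2cd4d and Pinlyp these are peaks that do not overlap. At Gm49027 the replicate 1 peak had a summit pileup of 51 fragments and the replicated peak, from the pooled reads, only 20. Different summits were therefore probably compared at Gm49027. At Armcx3 the summit pileups were 28 and 33 fragments over a local background of 7.24 and 2.02, and at Hgf 14 and 18 over 4.82 and 2.02, so the division by background made most of these gaps. Jrkl (pileups 15 and 20) and Mfsd4b2 (23 and 29) also had the higher background in replicate 1, and Armc9 (50 and 20), Map3k6 (46 and 17) and Kbtbd11 (30 and 11) in replicate 2. With 1 list per replicate these gaps have no test.

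**Figure D1:**
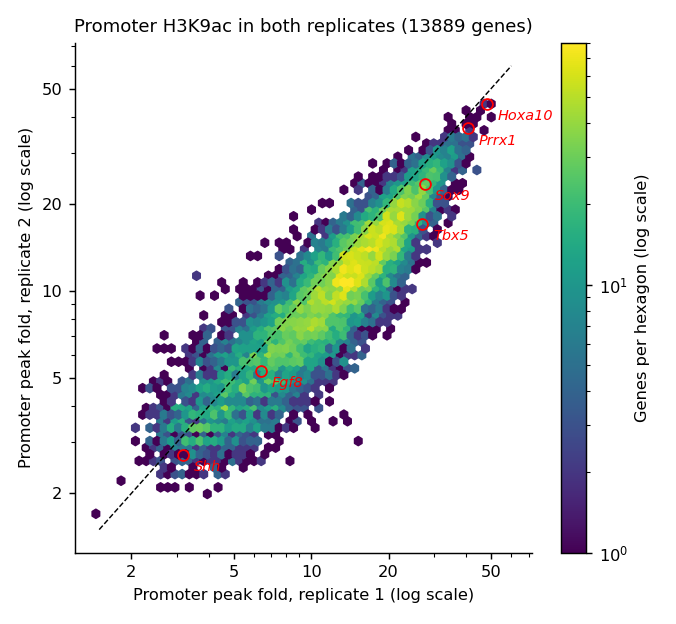
Fold of the strongest promoter peak in replicate 1 (x axis, log scale) and replicate 2 (y axis, log scale) for the 13889 coding genes with a peak in both lists, with the number of genes per hexagon as colour and the line of equal values dashed. Hoxa10 and Prrx1 lie near the top and Shh, at a mean fold of 2.95, near the bottom, and most genes lie below the line, with a median log2 ratio of 0.27.

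Of all peaks, 33.9% of those in replicate 1 (31133 of 91937) overlapped a peak of replicate 2 by at least 1 bp, and 46.6% of those in replicate 2 (34590 of 74158) overlapped one of replicate 1, with a Jaccard index of 0.399 over bases. Overlap followed peak strength: all peaks in the strongest 10% of either list were shared, against 9.52% in the weakest 10% of replicate 1 and 19.2% in that of replicate 2. Peaks of replicate 1 that were shared had a median summit pileup of 21 fragments, and those seen in it alone 11 (14 and 9 in replicate 2). Among the 20000 strongest peaks of each list, 80.9% and 87.9% were shared. Of the 29190 pooled peaks that overlapped a peak in both replicates, 28540 (97.8%) were in the replicated list, while 4685 of its peaks did not overlap both.

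Most replicated peaks lay at promoters. Of the 33219 replicated peaks on assembled chromosomes, 16954 (51.0%) were within 1 kb of a start site of a coding gene, against a mean of 3.14% over 1000 random placements on the same chromosomes (permutation p = 0.001, the smallest these placements can give). A further 11545 (34.8%) were distal, over 5 kb from any such start site, and 4720 (14.2%) lay between. In the longer lists of replicate 1 alone and replicate 2 alone the promoter share was 23.9% and 29.2%. Promoter peaks were stronger and wider than distal ones, with a median fold of 10.4 against 3.63, a median width of 1122.5 against 429 bp and a median summit pileup of 62 against 21 fragments. The differences in fold and in width each had a two-sided permutation p of 1e-05, the smallest that 100000 resamples can give. That in summit pileup was not tested, and peaks are not independent replicates. At least 1 replicated promoter peak was found at 13922 of 21851 coding genes (63.7%). Genes with a peak had CpG-richer promoters than genes without, with a median CpG observed/expected ratio of 0.727 against 0.177 and a GC content of 59.3% against 45.6% in 1 kb around the start site (permutation p = 1e-05 for both).

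Among promoter peaks the highest fold was 54.7 at Skida1 on chromosome 2 (18044093 to 18050242), followed by the peak over Hoxa10 (54.2), and by Tnrc18 (52.5) and the splicing factor gene Sfpq (50.2). The other genes among the 20 strongest promoter peaks, between 43.5 and 48.3, were Smad7, an inhibitor of TGF-beta signalling, Hnrnpu, Arid1a, Sox4, Nedd4, Actg1, Prrx1, Gas1, Setd1b, Rps19, Mex3c, Rbm39, Sox11, B230219D22Rik, Fbxo11 and Actb. The strongest distal peak, with a fold of 55.3, lay at an exon of the non-coding gene 1810026B05Rik, 14.2 kb from the nearest coding start site, that of Chd2 (chromosome 7, 73555965 to 73558668). The next lay in an intron of Bicral (54.6), at an exon of Zfhx3 (48.3), and at the microRNA gene Mirlet7i, 88.5 kb from Ppm1h (42.0). The remaining peaks of the 10 strongest, with folds of at most 37.5, had Ern1, Gpc5, Slc38a10, Hspa1b, Gigyf1 and Macf1 as nearest coding genes. In that order, they lay within 1 kb of start sites of the non-coding genes Gm22711, Mir17, 2810410L24Rik, 1110038B12Rik, Gm8066 and Gm12925. The peak nearest to Gpc5 overlapped no annotated gene but lay beside Mir17.

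All members of the limb transcription factor and limb signalling lists were marked. All 30 limb transcription factor genes had a replicated promoter peak (100%, exact 95% interval 88.4 to 100), against 63.7% of other coding genes (Fisher's exact test, two-sided, adjusted p = 1.7e-05 over the 20 lists). They included the hindlimb genes Pitx1 (26.5 ± 0.466, SD, n = 2) and Tbx4 (21.9 ± 5.77), the forelimb gene Tbx5 (22.1 ± 7.06), the dorsal determinant Lmx1b (27.8 ± 1.41), and Hand2 (32.4 ± 4.13) and Gli3 (29.9 ± 4.64), which act in anterior-posterior patterning. Against CpG-matched genes, chosen after seeing the data, this list passed with replicated peaks (87.1%, permutation test, adjusted p = 0.0272) and with replicate 2 alone (0.0343). It missed the threshold in the pooled list (89.6%, permutation test, adjusted p = 0.0719) and with replicate 1 alone (89.3%, 0.0622). All 30 genes were marked in both of these lists, so no higher share was possible. All 22 limb signalling genes were also marked (exact test, adjusted p = 0.000325; 88.7% in CpG-matched genes, where the call ended, permutation test, adjusted p = 0.179, chosen after seeing the data), from Ptch1, the hedgehog receptor (fold 36.4), Fzd2 (36.3) and Wnt5a (32.4) down to Fgf4 (3.63), Wnt3 (3.80), Dkk1 (3.48) and Shh (3.45). With all 22 marked, the share could go no higher, so the CpG-matched test could not have kept this call. Shh, made only in a small posterior part of the bud, had a summit pileup of 19 fragments (exact Poisson 95% interval 11.4 to 29.7) over its promoter on chromosome 5 (28466681 to 28467054), and Prrx1 264 (233 to 298). These intervals cover counting error only. Of the 20 chondrogenic genes, 19 were marked (exact test, adjusted p = 0.00361), all but Snorc, with folds of 26.4 at Sox9, 21.1 at Col2a1, the main cartilage collagen, 20.7 at Sox6 and 2.94 at Matn1.

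**Figure D2:**
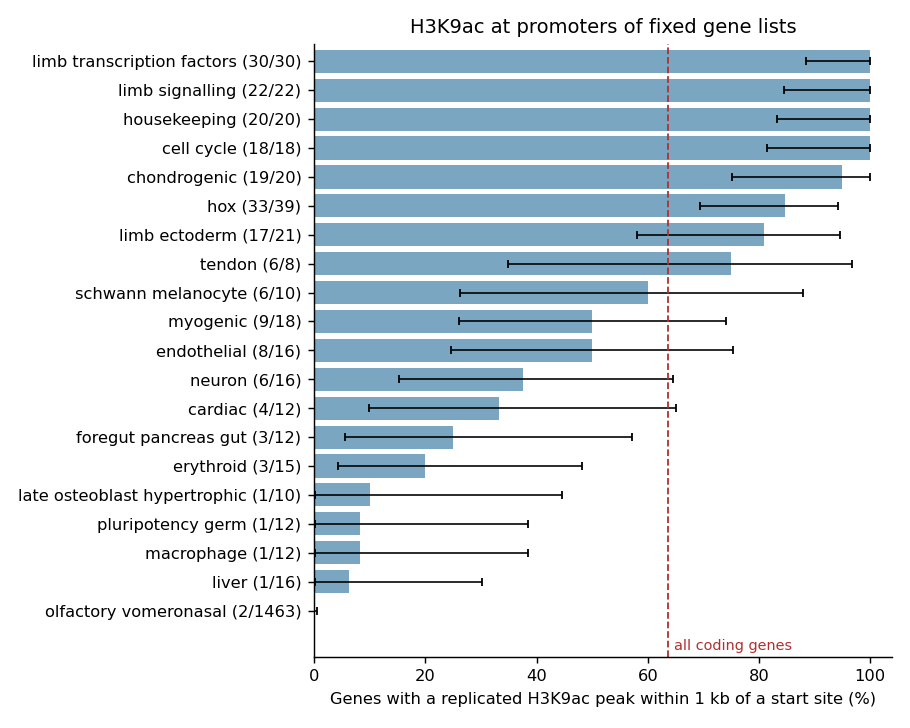
Share of each fixed gene list with a replicated H3K9ac peak within 1 kb of a start site (x axis, %), with marked and total members in parentheses and exact 95% binomial intervals as bars. The dashed line is the share among all coding genes, 63.7%; the lists run from 100% for limb transcription factors to 0.137% for olfactory and vomeronasal receptors.

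The Hox clusters, which pattern the limb along its axis, were marked at 33 of 39 genes (84.6%, exact 95% interval 69.5 to 94.1, adjusted p = 0.0114). All 11 HoxA genes and all 9 HoxD genes had a peak, against 8 of 9 HoxC genes and 5 of 10 HoxB genes, and the median fold of marked genes was 22.3 in HoxA, 21.1 in HoxD, 5.53 in HoxC and 3.97 in HoxB. The 5' genes of HoxA and HoxD were highest. A single peak of 25583 bp spanned Hoxa10 and Hoxa11 (chromosome 6, 52231357 to 52256939; fold 54.2), Hoxa9 had 41.4 and Hoxa13 32.1. One peak covered Hoxd11, Hoxd12 and Hoxd13 (chromosome 2, 74667048 to 74685863; fold 33.5), while Hoxd4 had 5.35 and Hoxd1 3.96. In HoxC the highest were Hoxc11 (14.5), Hoxc10 (10.7) and Hoxc9 (10.5). Hoxb1, Hoxb3, Hoxb5, Hoxb8, Hoxb13 and Hoxc13 had no replicated peak, and all but Hoxb13 had one in the list of replicate 1 alone. Because neighbouring Hox genes share peaks, the count fell to 29 of 39 when a peak was given only to its nearest start site, and the list then missed the threshold (exact test, adjusted p = 0.0945). Against CpG-matched genes, of which 83.4% had a peak, the call also ended (permutation test, adjusted p = 1.00). Both settings were chosen after seeing the data.

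**Figure D3:**
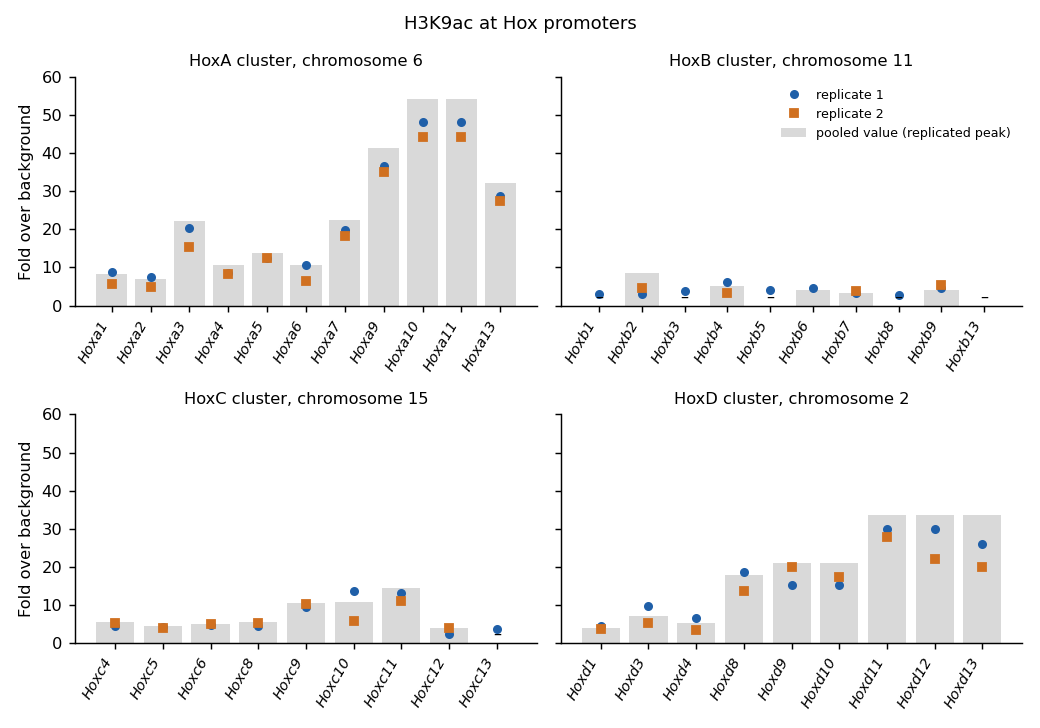
Fold over background of the strongest promoter peak at each Hox gene, by cluster in order of gene number (x axis), with the pooled value as bars, replicate 1 as circles and replicate 2 as squares; a dash marks a gene with no replicated peak. Hoxa9 to Hoxa13 and Hoxd11 to Hoxd13 stand between 32.1 and 54.2, and no marked HoxB gene exceeds 8.68.

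Markers of other cell types in or around the limb were marked in part. Of the 21 ectoderm genes 17 had a peak (81.0%, exact test, adjusted p = 0.144), with Tfap2a at a fold of 15.2, Fgf8 of the apical ridge at 6.56 and Sp8 at 3.80, while Trp63, Krt5, Krt14 and Esrp1 had none. In the pooled list 19 of the 21 had a peak, just past the threshold (90.5%, exact test, adjusted p = 0.04999). Of the 18 myogenic genes 9 had one (exact test, adjusted p = 0.271), among them the precursor genes Six1 (20.3), Eya1 (9.79), Lbx1 (5.18), Pax3 (4.26) and Pax7 (3.63) and the determination gene Myod1 (3.97). Myf5, Myog, Actc1, Ttn and Myh3 had none, and the peak at Mylpf (24.3) also lay at Tbc1d10b. In the list of replicate 1 alone 14 of the 18 had a peak (exact test, adjusted p = 0.536). Endothelial genes were marked at 8 of 16 (exact test, adjusted p = 0.334), from Fli1 (32.3) to Sox17 (3.00), with no replicated peak at Pecam1, Cdh5 or Tek. With replicate 1 alone 12 of the 16 had a peak (75% against 67.8% of other genes, exact test, adjusted p = 0.877). Tendon genes were marked at 6 of 8 (exact test, adjusted p = 0.756), Scx highest at 17.3, and Schwann cell and melanocyte genes at 6 of 10 (adjusted p = 0.756), where the peaks at Mpz (15.3) and Pmel (13.6) also lay at Sdhc and Cdk2.

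In the replicated list, genes of late bone, blood, liver, brain, gut, heart and germ cells were marked less often than other coding genes. Among 16 liver genes, such as Alb, Afp and Ttr, only Foxa2 had a peak (6.25%, exact 95% interval 0.158 to 30.2, adjusted p = 1.7e-05), and among 12 pluripotency and germ cell genes only Dazl (8.33%, adjusted p = 0.000382). Of 12 macrophage genes Aif1 alone was marked (exact test, adjusted p = 0.000382), and of 10 late osteoblast and hypertrophic cartilage genes only Sp7, an early osteoblast regulator (adjusted p = 0.00147), with Col10a1, Bglap and Spp1 lacking a peak. Erythroid genes had peaks at Klf1 (12.1), Nfe2 (9.81 ± 1.75, SD, n = 2) and Gypa (5.34) but at none of the 7 globin genes examined (3 of 15, exact test, adjusted p = 0.00147). Foregut, pancreas and gut genes were marked at 3 of 12 (Cdx2, Nkx2-1 and Sox21, at 2.59 to 3.97; exact test, adjusted p = 0.0182), neuronal genes at 6 of 16 (adjusted p = 0.0494) and cardiac genes at 4 of 12 (adjusted p = 0.0494), where the strongest peak, at Myl4 (33.5), also lay at Cdc27. Olfactory and vomeronasal receptor genes had peaks at 2 of 1463 (0.137%, exact 95% interval 0.0166 to 0.493), Olfr94 and Vmn1r4. The low counts depended on the comparison genes and on the peak list. With start sites of all annotated genes, 32.1% of which had a peak, only the receptor genes kept their low call. Liver (exact test, adjusted p = 0.0589) and pluripotency and germ cell genes (0.183) were among those that missed the threshold. Against CpG-matched genes, chosen after seeing the data, erythroid genes were not lower (20% against 16.1%, permutation test, adjusted p = 0.749), and the calls ended for late bone (adjusted p = 0.577), macrophage (0.452) and cardiac genes (0.179). For erythroid, late bone and macrophage genes the 95% range of the matched share reached 0. A list of their size with no marked member would still have lain within it, so these comparisons could show little. In the pooled list 11 of 16 neuronal genes had a peak, as often as other genes (68.8% against 68.0%, exact test, adjusted p = 1.00), and the calls ended for cardiac and foregut genes (58.3% each, 0.634). Likewise, with the list of replicate 1 alone, which is not restricted to replicated peaks, 6 of 12 macrophage genes (exact test, adjusted p = 0.313), 4 of 10 late bone genes (0.143), 9 of 16 neuronal genes (0.527), 8 of 12 cardiac genes (1.00) and 6 of 12 foregut genes (0.313) had a peak. With the list of replicate 2 alone, 6 of 12 cardiac genes (exact test, adjusted p = 0.404), 5 of 12 foregut genes (0.180), 4 of 12 pluripotency and germ cell genes (0.0492), 2 of 12 macrophage genes (0.00265) and 2 of 10 late bone genes (0.00918) had one. Liver genes had 3 of 16 in replicate 1 alone (exact test, adjusted p = 0.000385), pluripotency and germ cell genes 2 of 12 (0.00131), and the receptor genes 10 in replicate 1 alone and 12 in replicate 2 alone.

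Among marked genes, limb transcription factors and housekeeping genes had the higher peaks. The median fold was 20.4 over the 30 limb transcription factor genes against 13.1 in other marked genes (two-sided permutation test, adjusted p = 0.0003 over 12 lists), and 25.5 over the 20 housekeeping genes (adjusted p = 0.00012), all of which were marked, as were all 18 cell cycle genes (median 16.3, adjusted p = 0.186). Prrx1 (45.2), Tbx18 (39.2), Hand2 (37.3) and Twist1 (37.0) were highest among the former, and Actb (43.5), Eef1a1 (39.5) and Ywhaz (38.0) among the latter. Lower medians were found in the ectoderm (6.56, permutation test, adjusted p = 0.0194), myogenic (5.18, adjusted p = 0.0265) and neuronal lists (3.80, adjusted p = 0.0265). In the list of replicate 2 alone these 3 lists missed the threshold, at medians of 6.12, 4.63 and 3.80 against 10.1 (permutation test, adjusted p = 0.0584 each), and housekeeping genes had 16.3 (0.00247). In that of replicate 1 alone, Hox genes (8.68, permutation test, adjusted p = 0.0320) and endothelial genes (5.11, 0.0156) passed it, against a median of 12.2. In the replicated list the others did not pass the permutation test, at medians of 10.5 for Hox (adjusted p = 0.165), 11.7 for limb signalling (0.498), 8.81 for chondrogenic (0.0983), 7.34 for endothelial (0.108), 9.58 for tendon (0.348) and 7.68 for Schwann cell and melanocyte genes (0.165).

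Distal peaks gathered around limb regulators. Limb transcription factor genes with a promoter peak had a mean of 4.13 distal peaks assigned within 100 kb, 124 in all at 26 of 30 genes, against 0.612 at other marked genes (two-sided permutation test, adjusted p = 0.00012). Lmx1b had the most, 24, and the mean of the others was 3.45. Tbx5 had 9 and Tbx4 8. Limb signalling genes had a mean of 2.27 (permutation test, adjusted p = 0.00354), with 8 at Ror2, and chondrogenic genes 2.05 (adjusted p = 0.0114), with 11 at Runx3 and 9 at Col2a1. No other list passed the test: Hox genes had a mean of 0.697, ectoderm 1.29, myogenic 1.67, tendon 2.17, endothelial 1.63, Schwann cell and melanocyte 0.833, neuronal 0.667, housekeeping 0.9 and cell cycle genes 0.5. With start sites of all annotated genes the means fell to 1.63 for limb transcription factors (49 peaks at 19 genes), 1.18 for limb signalling and 1.58 for chondrogenic genes, against 0.285 at other marked genes, and all 3 lists still passed, with myogenic genes as a further one (1.56, permutation test, adjusted p = 0.0274). In the longer lists of single replicates all means rose, with the same 3 lists passing: limb transcription factors had 12.2 in replicate 1 alone and 9.53 in replicate 2 alone, limb signalling 7.91 and 5.52, chondrogenic 7.15 and 4.53, and other marked genes 2.74 and 1.99. Hox genes had 1.29 and 1.16 in these lists, below other marked genes (2.76 and 2.01), without passing the test. With distal peaks counted from over 2.5 kb, tendon genes also passed (3.00, permutation test, adjusted p = 0.0496). A distal peak was assigned by distance alone, and its target was not measured.

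Limb regulators also held the widest domains. After peaks up to 1 kb apart were merged, 12120 of 25487 domains held a coding start site, and the widest 5% of these were at least 4280 bp wide. Of the limb transcription factor genes in a domain, 23 of 29 were in this widest class (Fisher's exact test, two-sided, adjusted p = 7.08e-23), as were 16 of 23 Hox genes (adjusted p = 1e-14), 9 of 21 limb signalling genes (adjusted p = 3.39e-06), 6 of 17 chondrogenic genes (Col2a1, Col9a3, Runx2, Sox5, Sox6 and Sox9; adjusted p = 0.000629) and 5 of 18 housekeeping genes (adjusted p = 0.00564). With merging up to 3 kb the calls ended for chondrogenic (23.5%) and housekeeping genes (22.2%; exact test, adjusted p = 0.0582 each). With peaks of replicate 2 alone, tendon genes also passed (2 of 5, exact test, adjusted p = 0.0494) where they had 1 of 6 in the replicated list. Neighbouring Hox genes share domains, so their counts are not independent. A distal peak can be part of a domain that holds a start site, as the distal peak at Zfhx3 was. Counts of distal peaks and domain widths are therefore not separate results. The widest domain held start sites of the HoxA genes from Hoxa5 to Hoxa13 (chromosome 6, 52201198 to 52269115, 67.9 kb). It also held a start site of Hoxa3 but none of Hoxa4. The next spanned HoxD from Hoxd9 to Hoxd13 (chromosome 2, 74663121 to 74701182, 38.1 kb). The others of the 10 widest lay at Bahcc1 (22.5 kb), Lmx1b (21.4 kb), Zfhx3 (20.9 kb), Tbx5 (18.4 kb), Prdm16 (16.4 kb), Ebf3 (16.1 kb), Tnrc18 (15.9 kb) and Tbx2 (15.7 kb).

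The X chromosome stood apart from the autosomes. It had 3.94 replicated peaks per Mb, against 8.13 on chromosome 14 to 25.3 on chromosome 11, and 44.9% of its coding genes had a promoter peak, against 52.0% to 77.9% on single autosomes. Among marked genes the median fold was 7.60 on X, at 426 genes, and 12.2 to 14.5 on single autosomes. In the replicates' own lists the X median was 7.16 in replicate 1, where autosomal genes had 12.5, and 6.19 in replicate 2, where they had 10.3. The X-linked housekeeping genes Pgk1 (7.82 ± 3.57, SD, n = 2) and Hprt (12.8 ± 0.119, SD, n = 2) and the X-linked limb gene Zic3 (6.63 ± 0.486, SD, n = 2) were among them. The Y chromosome had 3 peaks. These values were described without a test.

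**Figure D4:**
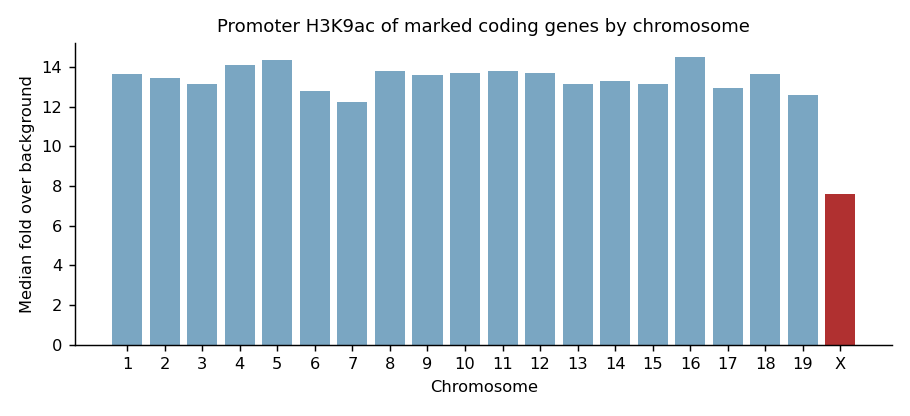
Median fold over background of the strongest promoter peak among marked coding genes (y axis), for each autosome and X (x axis), from the replicated list. The autosomes lie between 12.2 and 14.5 and X, in red, at 7.60.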

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

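Of the replicated peaks, 6 lay on unplaced or unlocalized scaffolds, which the comparisons by gene and chromosome left out; they are given here because signal was present outside the regions compared. The strongest, on an unlocalized scaffold of chromosome 4 (16135 to 17172), had a fold of 9.84 and a summit pileup of 56 fragments. Another 3 lay on a scaffold assigned to X, at folds of 3.63 to 5.70, and the remaining pair on an unplaced scaffold had pileups of 181 and 167 fragments at folds of only 1.66 and 1.73.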

How the results depend on the processing

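Of 539 results recomputed under other settings, 425 kept their direction and side of the threshold or stayed within their interval, 41 became weaker, 11 stronger, 17 moved and 45 turned direction. None of those that turned passed the threshold after turning. A call in the replicated list turned for neuronal genes (pooled list, all annotated genes), cardiac genes (all annotated genes) and erythroid genes (CpG-matched genes); the others had no call before either. The nearest start site, CpG-matched (in all peak lists) and territory-matched settings were chosen after seeing the data. No paired analysis was possible because there is a single group. The calls of the promoter share, of promoter against distal peaks and of CpG content were the same under every setting run. Lists of single replicates are not restricted to replicated peaks, and their median summit pileup of 10 to 12 fragments limits what they show for weak peaks. Start sites of all annotated genes add many unmarked genes to the background.

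Overlap of replicate 1 with replicate 2 was 24.9% with at least 50% of the peak covered, 22.4% with this asked of both peaks, 42.0% at a −log10 q of at least 2, and 80.9% for the top 20000. For replicate 2 the values were 40.1%, 27.8%, 56.4% and 87.9%. Membership in the replicated list, with at least 50% of the peak covered, was 38.8% for replicate 1 and 48.6% for replicate 2, and of replicated peaks 87.9% lay in replicate 1 and 69.5% in replicate 2. The replicate correlation was 0.898 with 500 bp around start sites and 0.898 at a −log10 q of at least 2. Genes with a promoter peak were 68.0% in the pooled list, 32.1% with all annotated genes, and 65.2% to 67.8% when leaving out 1 replicate.

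The share of list members with a peak in the pooled list was 90.5% for ectoderm genes, a call gained, and, with calls lost, 68.8% for neuronal, 58.3% for cardiac and 58.3% for foregut genes. Leaving out 1 replicate gave 50% to 66.7% for cardiac, 41.7% to 50% for foregut, 20% to 40% for late bone, 16.7% to 50% for macrophage and 37.5% to 56.3% for neuronal genes. Against all annotated genes the call was gained for ectoderm (81.0%) and tendon (75%) and lost for late bone (10%), erythroid (20%), macrophage (8.33%), neuronal (37.5%), liver (6.25%), cardiac (33.3%), foregut (25%) and pluripotency genes (8.33%). It was lost for cardiac genes (33.3%) at 500 bp, for neuronal (43.8%) and cardiac genes (41.7%) at 2.5 kb, and with the nearest start site only for Hox (74.4%), neuronal (37.5%) and cardiac genes (33.3%). Against CpG-matched genes it was lost for Hox (1.17 percentage points above), limb signalling (11.3), erythroid (3.86), housekeeping (7.35) and cell cycle genes (3.71), and for late bone (-14.7), macrophage (-12.9) and cardiac genes (-16.8). Limb signalling, housekeeping and cell cycle genes were all marked, so their share could go no higher and this comparison could not have kept their calls. For erythroid, late bone and macrophage genes, the 95% range of the matched share reached 0.

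The median fold of Hox genes was 8.48 in the pooled list, a call gained. Leaving out 1 replicate gave medians of 7.29 to 8.68 for Hox, 5.41 to 6.12 for ectoderm, 3.86 to 4.63 for myogenic, 5.11 to 6.37 for endothelial and 3.45 to 3.80 for neuronal genes. Distal peaks were gained as a call for myogenic genes with all annotated genes (1.56), for tendon genes over 2.5 kb (3.00) and for Hox genes against territory-matched genes (0.521 above). Widest domains were gained for cell cycle genes in the pooled list (29.4%), ranged from 20% to 40% for tendon genes when leaving out 1 replicate, and were lost with merging up to 3 kb for chondrogenic (23.5%) and housekeeping genes (22.2%).

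Values that turned direction without a call before or after were these. Share of members with a peak: myogenic 83.3% in the pooled list, 77.8% without replicate 2 and 50% with all annotated genes, endothelial 75% without replicate 2 and 50% with all annotated genes, Schwann cell and melanocyte 60% with all annotated genes and 14.1 points above CpG-matched genes. Median fold of limb signalling: 11.1 without replicate 1. Mean distal peaks: Hox 1.24 in the pooled list, 1.16 and 1.29 without replicate 1 and 2, and 0.212 with all annotated genes; housekeeping 2.20, 1.65 and 2.45 in the same 3 lists; Schwann cell and melanocyte 2.40 without replicate 2, 0 with all annotated genes and 0.5 within 50 kb; neuronal 0.5 at a −log10 q of at least 2, 0.5 within 50 kb and -0.0669 against territory-matched genes; endothelial 0.25 and cell cycle 0.444 with all annotated genes, and cell cycle 1 over 2.5 kb. Widest domains: myogenic 20% in the pooled list, 11.1% without replicate 2 and 14.3% with 3 kb merging, cell cycle 5.88% with all annotated genes, tendon 0% without merging. Points above or below CpG-matched genes: myogenic 18.7 in the pooled list, 0.596 without replicate 1 and 14.0 without replicate 2; macrophage 2.41 and cardiac 1.89 in the pooled list; Hox -2.28 and ectoderm -1.89 without replicate 1; macrophage 18.8, cardiac 10.2, late bone 5.86, endothelial 8.13 and Schwann cell and melanocyte -1.6 without replicate 2. Leaving out the other replicate kept the direction: the share was 61.1% for myogenic genes without replicate 1, the median fold 9.82 for limb signalling without replicate 2, and the points against CpG-matched genes were -8.47 for macrophage, -2.30 for cardiac, -8.88 for late bone, -12.2 for endothelial and 1.85 for Schwann cell and melanocyte genes without replicate 1, and 10.7 for Hox and 9.76 for ectoderm genes without replicate 2.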

Other observations

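The tests and gene groups in this part were chosen after the main results had been seen, and the bounds for the tests of explanations were written before those tests were run, except for the CpG-matched tests list by list, whose bounds were written after their values were seen. Replicated peaks also marked genes that make no protein. Counting only those with every start site over 5 kb from a coding one, a peak lay within 1 kb of 456 of 5213 lincRNA genes (8.75%), 155 of 1697 antisense genes (9.13%), 97 of 427 processed transcript genes (22.7%) and 99 of 1733 microRNA genes (5.71%), against 97 of 9180 processed pseudogenes (1.06%). Among the strongest were 1810026B05Rik (fold 55.3; 47.1 ± 0.758 over both replicates, SD, n = 2), the peak beside the microRNA gene Mir17 on chromosome 14 (115040191 to 115042726; fold 35.9), Dnm3os, the antisense RNA that hosts microRNAs and is transcribed in skeletal mesenchyme (30.2; chromosome 1, 162217539 to 162222298), Snhg6 (29.5), Dleu2 (27.1) and Dancr (24.6). These genes were named for their values, after these had been seen. The peaks at 1810026B05Rik and Mir17 are the same as the strong distal peaks nearest to Chd2 and Gpc5 named above.

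Gene families grouped by symbol differed in how often they lay in the widest 5% of domains holding a start site. Of 36 families tested, 5 passed (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted). The replication-dependent histone genes of the Hist1 cluster had 22 of 41 members there (exact test, adjusted p = 1.15e-15), where neighbouring genes share domains. T-box genes had 6 of 11 (Tbx2, Tbx3, Tbx4, Tbx5, Tbx15 and Tbx18; exact test, adjusted p = 0.000228), Frizzled receptors 5 of 10 (adjusted p = 0.00146), histone methyltransferases named Kmt 4 of 8 (adjusted p = 0.00564) and Sox genes 5 of 14 (adjusted p = 0.00575). All 6 T-box genes were already counted in this class with the limb transcription factors, so theirs is not a separate result. Sox5, Sox6 and Sox9 were counted there with the chondrogenic genes, and Fzd2 with limb signalling. Solute carriers had 5 of 233 (exact test, adjusted p = 0.0584), ribosomal protein genes named Rpl 2 of 45 (adjusted p = 1.00) and genes named Usp 0 of 48 (adjusted p = 0.205).

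Marked X-linked genes had a lower fold than marked autosomal genes, 7.60 against 13.5, and their promoters had a lower CpG observed/expected ratio, 0.623 against 0.729. Against autosomal genes matched on CpG observed/expected, the ratio of medians was 0.673 (95% bootstrap interval 0.620 to 0.739), higher than the unmatched 0.564 but below 0.75. This argues against CpG observed/expected, as measured around the 5'-most start site, as the whole cause. GC content was not matched. The summit pileup itself was lower, by a matched ratio of 0.646 (0.592 to 0.703), which argues against division by a genome-wide background as the whole cause. A candidate explanation is that each cell has a single active X, which would give a ratio of 0.5 if an active X allele carries as much H3K9ac as an autosomal one: the pileup above background had a matched ratio of 0.620 (0.561 to 0.682), above 0.5, and this explanation could not be decided. Only genes with a promoter peak entered these ratios, 44.9% of X genes and 65.1% of autosomal genes. Weak X promoters that missed the peak threshold are left out, which can raise the ratio above its value for all X genes. Sex was pooled in both samples, so no comparison of male and female tissue was possible, and differences in read mapping between X and autosomes were not tested.

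Limb transcription factor genes have large surroundings, a median of 142 kb of distal sequence to which they hold the nearest coding start site against 40.8 kb for other marked genes, and this may add distal peaks. Against genes in the same bin of that length, their mean of 4.13 distal peaks was 4.57 times the matched mean of 0.905 (permutation p = 1e-05, the smallest these draws can give), which argues against territory as the whole cause. The mean was 3.45 without Lmx1b. Limb signalling genes also stayed above matched genes, at 2.46 times (permutation test, adjusted p = 0.0363), as did chondrogenic genes, at 2.64 times (adjusted p = 0.0409). Hox genes, with a median territory of only 1.33 kb, were at 3.96 times (permutation test, adjusted p = 0.0134). Their median was 0 distal peaks per gene, with 23 peaks at 11 of 33 genes. Without matching, they had fewer distal peaks than other marked genes in the pooled list (1.24 against 2.71) and in both lists of single replicates. No biological explanation was tested.

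The low share of late bone, blood, macrophage, neuronal, liver, heart, gut and germ cell genes was set against genes matched on CpG observed/expected. These 8 lists were grouped because each was called low in the replicated list, so their joint gap (20 of 105 members, 19.0%, against 42.7%; 23.7 percentage points) cannot exclude CpG-poor promoters, and it was only 9.64 points in the pooled list and 9.49 with replicate 1 alone (16.8 with replicate 2 alone). List by list, with p adjusted over all 20 fixed lists, pluripotency and germ cell genes lay below matched genes in all 4 peak lists (8.33% against 58.4% with replicated peaks, permutation test, adjusted p = 0.0001). The smallest gap was -27.1 points, with replicate 2 alone (permutation test, adjusted p = 0.0474). These values argue against CpG observed/expected as the whole cause for this list, though GC content was not matched. The 4 peak lists come from the same 2 samples and are not independent of each other. Erythroid genes were marked as often as matched genes or more in all 4 lists (20% against 16.1% with replicated peaks, 3.86 points, the smallest difference), so CpG observed/expected may account for their low share. With replicated peaks, the 95% range of the matched share reached 0 for erythroid, late bone and macrophage genes. A list with no marked member would still have lain within it. For the other 6 lists the explanation by CpG observed/expected stays open, since the gap passed in some peak lists or in none. The highest differences were -27.5 points for liver, -10.2 for neuronal, -0.310 for foregut, 5.86 for late bone, 10.2 for cardiac and 18.8 for macrophage genes.

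With replicated peaks, neuronal (37.5% against 74.9%, permutation test, adjusted p = 0.0003), liver (6.25% against 37.5%, 0.0163) and foregut genes (25% against 53.3%, 0.0163) lay below CpG-matched genes. Neuronal genes did not pass in the pooled list (permutation test, adjusted p = 0.413). Liver genes missed the threshold in the pooled list (-27.9 points, permutation test, adjusted p = 0.0736) and with replicate 1 alone (-27.5 points, 0.0653), with gaps nearly as large as the -31.2 points of the replicated list. Foregut genes passed in none of the other lists. Among the limb lists, the same matching kept chondrogenic genes (95% against 60.1%, permutation test, adjusted p = 0.0002), which passed in all 4 peak lists. Limb transcription factors passed with replicated peaks (100% against 87.1%, permutation test, adjusted p = 0.0272) and with replicate 2 alone (0.0343), but not in the pooled list (100% against 89.6%, 0.0719) or with replicate 1 alone (100% against 89.3%, 0.0622). With replicated peaks the matching ended the call for Hox (84.6% against 83.4%, permutation test, adjusted p = 1.00) and limb signalling genes (100% against 88.7%, adjusted p = 0.179). A share of 100% is the highest possible, so the matched test could not have kept the call of limb signalling genes.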
